A study of Mus musculus with 4 samples.

How the data were processed

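RNA from the inguinal mammary gland of mice at postnatal day 10 was hybridised to 4 Affymetrix mouse expression arrays, 1 per sample. The labels give 2 wild-type and 2 global knockout samples, each called a biological replicate. The knockout removes Mt1-mmp, the gene listed on the array under the symbol Mmp14, which encodes a membrane-anchored matrix metalloproteinase. Knockout and wild-type mice were littermates of an outbred background, per the labels. The whole gland was homogenised without separating its cells, so epithelium, fat, vessels, nerve and immune cells all contributed RNA. Total RNA was extracted with an organic solvent, cleaned on columns, amplified and labelled with biotin by a kit that primes from the transcript's 3-prime end, per the labels' protocols.

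The authors summarised the array probes with RMA in the R package affy, per the submitters' processing notes, which name no version of either. RMA corrects background, equalises the distributions of the arrays and gives a single value per probe set, so a shift common to most genes would not remain visible. The deposited values are log2 expression values. That scale was not stated and was read from the values, which ran from 3.20 to 13.6 in wild-type replicate 1 and had array medians of 4.92, 4.92, 4.92 and 4.98. No detection calls were used, and the number of arrays limits the precision. Low values lie near the background of the array, where RMA compresses differences, so a fold against such a value is best read as a lower limit.

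The value table held 45141 probe sets, of which 104 were controls. Gene names came from an annotation of the array design, which listed 28898 probe sets with 1 gene, 551 with several genes and 15692 without a gene. Only probe sets with 1 gene were named. Gene identifiers of 28689 of them matched a RefSeq gene table of the assembly GRCm38.p6, used for names and for which genes neighbour each other, and 0 symbols needed updating. For each of the 17097 genes the probe set with the highest mean over the 4 arrays was used. Genes whose mean was at least 4.94, the median over all probe sets, were tested, which left 11078 genes.

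Knockout and wild-type samples were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited values, no covariate and Benjamini-Hochberg adjustment at 0.05. Gene lists were compared with limma's camera, which asks whether a list's genes were shifted relative to all other genes, with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over 42 lists. The 43 lists, 18 of cell type markers and 25 of pathways, held 866 entries, of which 764 had a gene on the array. The Y-linked list had 0 tested members and was left out of the tests. The lists, the tests of genes and lists and the rule for naming genes were fixed before the data were examined, as were the alternatives except the one without genes near Mmp14. The tests of possible technical sources were chosen after the results were seen. Camera with a correlation estimated from the arrays and the fry rotation test were run as alternatives. Within each list, p-values were also adjusted over the list alone. That adjustment does not span the lists and changes p little in a list of few genes. It passed 92 genes in 23 lists, where 21.8% of all tested genes had an unadjusted limma p under 0.05.

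The rule named the targeted gene and, in each direction, 10 genes. Genes past the threshold came before others, and open places went to the smallest p among genes whose groups did not overlap. Symbols that are only clone names were skipped, which removed 1 gene among those lower. Up to 4 genes with the smallest p were named per list, and all genes of a list that passed where these were 5 or fewer. Mmp15, which the rule also named, was not analysed here because no single-gene probe set was listed for it. Genes named outside this rule are said to be so.

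Other alternatives were no brightness filter, a filter at the 75th percentile, the mean of a gene's probe sets, leaving out probe sets that can match several transcripts, 3 further scalings (median centring, cyclic loess and quantile normalisation), an intensity trend, a robust prior, array weights, the replicate number as a block, each array left out in turn, other thresholds and tests of single probe sets. Control probe sets of actin and Gapdh were compared between their 3-prime and 5-prime ends.

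The tests were checked on simulated data. Among 11078 simulated genes, 200 were given known differences in groups of 40. Of those lower by 3 or by 2 on the log2 scale limma called 85.0% and 80.0%, of those higher by 2 it called 82.5%, and of those lower or higher by 1 it called 20.0% and 25.0%, with 11 false calls. Each simulated gene had the same spread in both groups. The real knockout arrays differed by a median of 0.214 and the wild-type arrays by 0.0785, so these shares need not hold for the real arrays. There, 16 genes were at least 4-fold higher and 36 lower without overlap, and 0 were called. A simulated list of 18 genes lower by 1 was called by camera with the preset correlation, while 0 of 41 unshifted lists were called. The simulated genes varied independently, whereas the correlation estimated from the arrays was 0.977 for the cell cycle list and 0.472 for cholesterol synthesis. The simulation therefore could not show how often camera wrongly calls lists whose genes vary together. With an estimated correlation the shifted list had an adjusted p of 0.305 and was not called. Medians of gene groups were compared with 10000 random lists matched on mean expression or given 95% bootstrap intervals in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Both drew genes and not animals, so they leave out the spread between animals. The random lists held independently drawn genes, whose medians can vary less than those of co-regulated genes. Plots were drawn with matplotlib 3.10.9.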

Results

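Expression was measured in the intact inguinal mammary gland of 10-day-old mice that lacked Mt1-mmp (Mmp14) and of wild-type littermates, with 2 arrays per genotype. Mmp14 is a collagen-degrading protease held in the cell membrane. The comparison asks which transcripts of the early postnatal gland, with its epithelium and surrounding fat pad, differ when the protease is missing. The arrays had near-equal medians of 4.92, 4.92, 4.92 and 4.98 (log2).

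Mmp14 was 8.40-fold lower in the knockout. Its brighter probe set gave 8.92 and 8.73 in the wild-type arrays and 5.83 and 5.68 in the knockout arrays, a difference of -3.07 ± 0.12 on the log2 scale (SE, n = 2 per group). A dimmer probe set gave 6.11 and 5.87 against 4.32 and 4.31, a difference of -1.67, or 3.18-fold. Both knockout arrays thus lay below both wild-type arrays in either probe set. In limma the brighter set had a Benjamini-Hochberg adjusted p of 0.0738, which did not pass 0.05. It passed with adjusted p = 0.00449 without knockout replicate 1 and 0.0216 without knockout replicate 2, where the lone knockout array is assumed to vary like the wild-type group. Whether either probe set lies in the deleted part of the gene is not given, so the values check the labels only as far as the transcript was lost.

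Among genes higher in both knockout arrays, those with the smallest p were the sialyltransferase gene St6galnac5, the acyl-CoA thioesterase gene Acot1, Net1 and the mast cell protease gene Mcpt4. St6galnac5 was 9.35-fold higher (log2 3.22 ± 0.15, SE, n = 2 per group), Net1 6.47-fold (2.69), Acot1 5.83-fold (2.54) and the annexin gene Anxa8 5.03-fold (2.33). Mcpt4 (1.85), Rassf6 (1.88), Dixdc1 (1.60), the mitochondrial sodium and calcium exchanger gene Slc8b1 (1.36), the lysine methyltransferase gene Etfbkmt (1.28) and the transcription factor gene Pou3f1 (1.23) completed the 10. Another probe set of Dixdc1 differed by only 0.14. Among genes lower in both knockout arrays were the membrane receptor gene Paqr9 at 11.4-fold (log2 -3.51 ± 0.22), the ribonuclease gene Rnase2a at 9.67-fold (-3.27), the secretory pathway kinase gene Fam20c at 6.05-fold (-2.60) and Ppp1r3b, which encodes a subunit that directs a phosphatase to glycogen, at 5.25-fold (-2.39). Zfp971 (-1.99), the aggrecan-degrading protease gene Adamts5 (-1.80), the interferon-induced gene Rsad2 (-1.81), the lipolysis inhibitor gene G0s2 (-1.48) and the red cell enzyme gene Bpgm (-1.43) followed. The histone gene H3c15 was also lower (-3.80 ± 0.28), but it belongs to a family of near-identical genes, as does Acot1 with its neighbouring paralogs, so neither can be assigned to a single gene with certainty.

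No gene passed the threshold, so these 20 differences are values that did not pass. With limma and Benjamini-Hochberg adjustment 0 of 11078 genes were higher and 0 were lower, and the smallest adjusted p was 0.0738, against 1074 higher and 1337 lower at an unadjusted p under 0.05, or 21.8% where chance gives 5%. At an adjusted p under 0.10 there were 7 higher and 10 lower genes, but that count moved with the settings, from 0 and 0 with array weights to 126 and 146 after cyclic loess and 163 and 196 with the 75th percentile brightness filter. The groups did not overlap for 58.8% of genes, where chance gives 33.3% for 2 against 2, with 2910 genes higher and 3605 lower in both knockout arrays. Of these, 134 were at least 2-fold higher and 235 at least 2-fold lower. The chance shares of 33.3% and 5% are averages. Because genes vary together, the share seen in a single set of arrays can lie well above them without an effect of genotype. The count at 0.05 depended on the knockout arrays. Limma called 1455 genes higher and 2725 lower without knockout replicate 1, and 746 higher and 553 lower without knockout replicate 2, with the lone array assumed to vary like the wild-type pair. The knockout arrays differed from each other by a median of 0.214 (log2) and the wild-type arrays by 0.0785, and 560 against 90 genes lay more than 2-fold apart. The 2 knockout arrays correlated at r = 0.925 across genes and the 2 wild-type arrays at 0.992, although genes are not independent replicates. The knockout arrays also differed in tissue markers, described further on, with skeletal muscle at a median of 5.49 above the wild-type mean in knockout replicate 2 and epidermis and hair follicle at 2.37 in knockout replicate 1, and no comparison was adjusted for these.

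**Figure D1:**
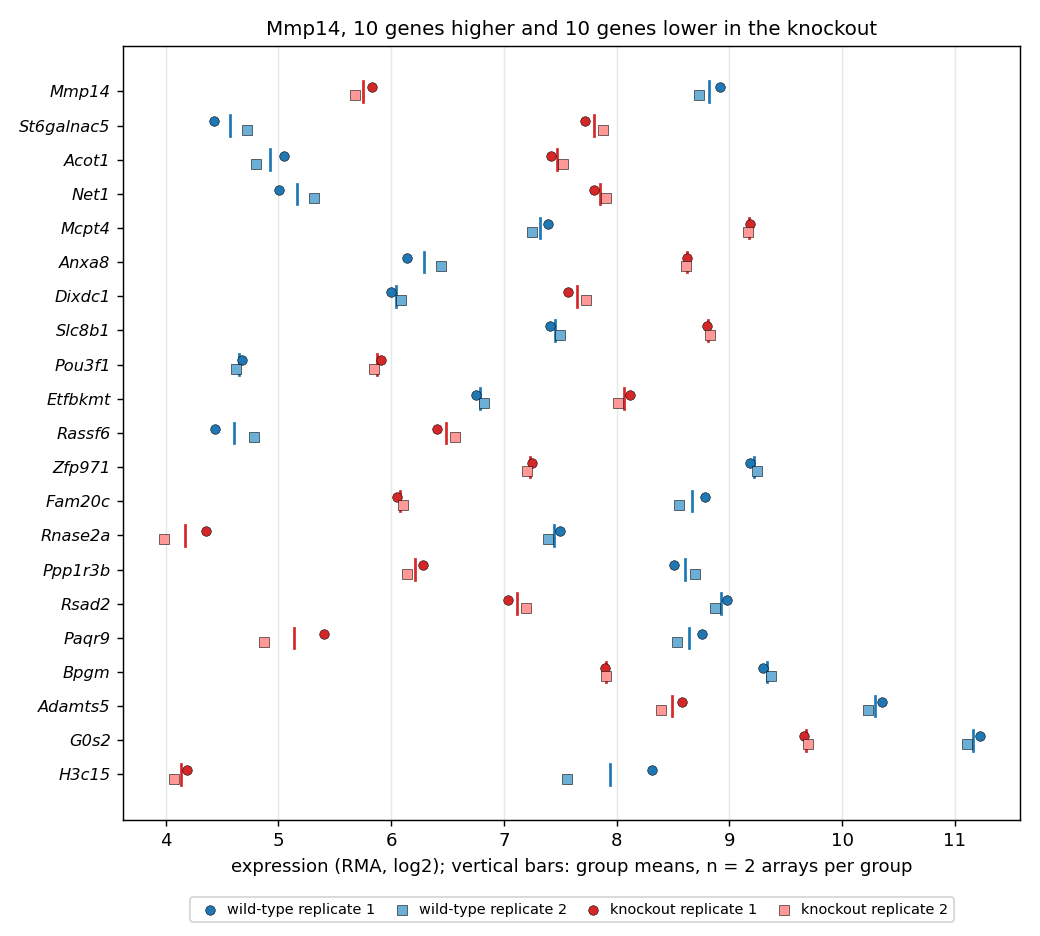
Expression (RMA values, log2, horizontal axis) of Mmp14, the 10 genes higher and the 10 genes lower in the knockout (vertical axis) in each of the 4 arrays. Points are arrays, short vertical bars are group means, and in each gene both knockout arrays lie on the same side of both wild-type arrays, as for Mmp14 with 5.83 and 5.68 against 8.92 and 8.73.

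Genes of lipid and sterol synthesis fell as groups in the knockout, with camera adjusted p = 0.0028 for fatty acid and triglyceride synthesis and 1.3e-04 for cholesterol synthesis. For both lists the call was lost, with adjusted p = 0.852 with an estimated correlation. In the fatty acid and triglyceride list 17 of 21 genes were lower, with a median of -0.51 (-0.55 in knockout replicate 1 and -1.15 in knockout replicate 2), and the fatty acid synthase gene Fasn had 11.7 and 11.7 in wild type against 9.80 and 8.32 in the knockout (log2 -2.68 ± 0.54, SE, n = 2 per group). Acss2 (-2.87 ± 0.43) and Acly (-1.11 ± 0.10), which make acetyl-CoA, and the citrate carrier gene Slc25a1 (-1.02 ± 0.18) were lower as well. In the cholesterol synthesis list 17 of 18 genes were lower, with a median of -1.02 (-0.65 and -1.26 in the knockout replicates), among them Nsdhl (-1.91 ± 0.27), Sc5d (-1.86 ± 0.15) and the HMG-CoA synthase gene Hmgcs1 (-1.08 ± 0.15). The exception was the squalene synthase gene Fdft1, higher by 0.83 ± 0.12. A further probe set of Sc5d was lower by a similar amount (-2.04), while another differed by 0.01. Of the fatty acid list 0 members passed over all genes and 6 passed lower when adjusted over the list alone, and of the cholesterol list 0 passed over all genes and 9 passed lower and 1 higher over the list alone. Skeletal muscle markers, described further on, stood at 5.49 above the wild-type mean in knockout replicate 2, the array in which both lists were lower. In knockout replicate 1 both lists also lay below the wild-type mean, at -0.55 and -0.65, but epidermis and hair follicle markers stood at 2.37 above it there.

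Markers of brown and beige adipocytes also fell as a group (camera adjusted p = 0.0040, but adjusted p = 0.852 with an estimated correlation). Of 17 brown and beige markers 14 were lower, with a median of -0.73 (-0.71 and -0.74 in the knockout replicates). The thyroid hormone deiodinase gene Dio2 (-1.52 ± 0.14, SE, n = 2 per group), the lineage regulator gene Prdm16 (-0.73 ± 0.09) and the respiratory subunit genes Cox7a1 (-0.93 ± 0.13) and Cox8b (-0.71 ± 0.11) were lower. Ucp1, the uncoupling protein gene of heat-producing fat, singled out after its values were seen, had 12.1 and 11.9 in wild type and 10.4 and 7.37 in the knockout (-3.11 ± 1.10). Skeletal muscle markers stood at 5.49 above the wild-type mean in knockout replicate 2, the array with the lower Ucp1 and Lep. Tbx1, also singled out afterwards, was higher by 0.56. White adipocyte markers were not called (camera adjusted p = 0.434). Of 14 white markers 10 were lower and 4 higher, with a median of -0.13. The leptin gene Lep had 10.7 and 10.7 against 6.95 and 4.48 (-5.00 ± 0.89), and the triglyceride synthesis gene Dgat2 differed by -2.19 ± 0.17, whereas Adig was higher by 0.82 ± 0.10 and Cebpa by 0.28 ± 0.11. No member of the brown and beige list passed over all genes, and 8 lower and 1 higher, Tbx1, passed when adjusted over the list alone. Without knockout replicate 1 the list's adjusted p was 0.0774. Of the white list no member passed over all genes, and Lep and Dgat2 (lower) and Adig (higher) passed when adjusted over the list alone.

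**Figure D2:**
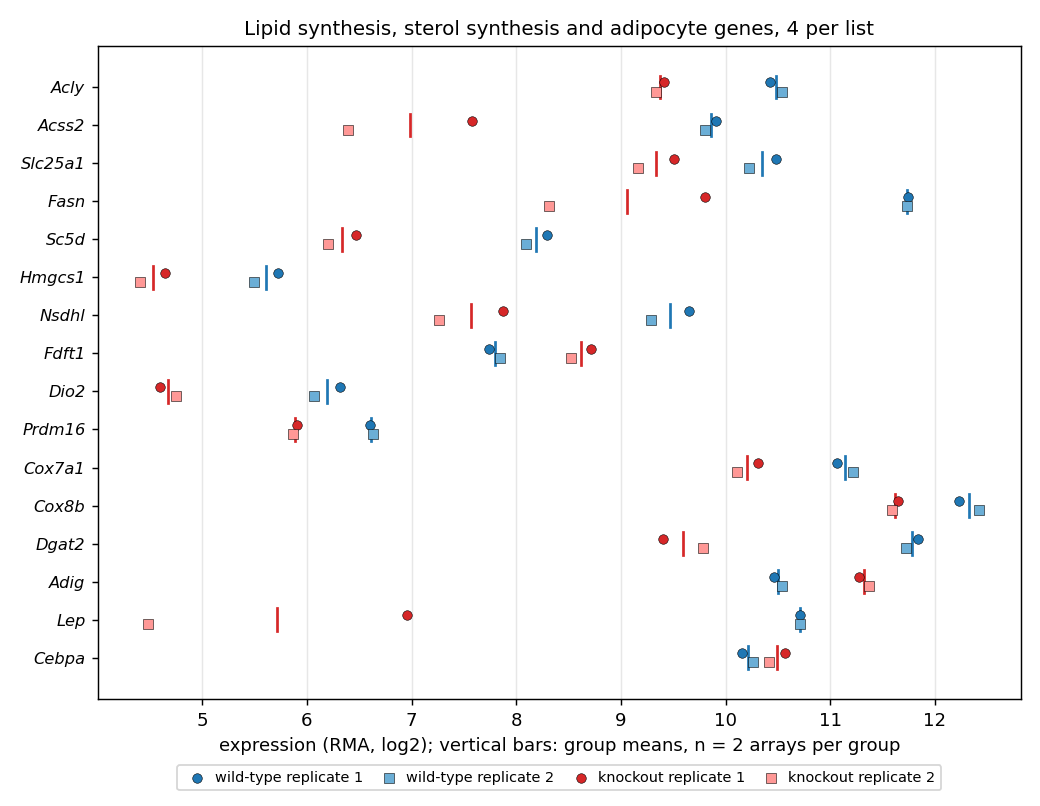
Expression (RMA values, log2, horizontal axis) of the 4 genes with the smallest p in each of the fatty acid and triglyceride synthesis, cholesterol synthesis, brown and beige adipocyte and white adipocyte lists (vertical axis, in that order) in each of the 4 arrays. Points are arrays and short vertical bars are group means; Lep shows the widest gap, from 10.7 in both wild-type arrays to 6.95 and 4.48, while Fdft1, Adig and Cebpa are higher in the knockout.

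Oxidative phosphorylation genes fell together by a small amount (camera adjusted p = 0.0019, but adjusted p = 0.852 with an estimated correlation). All 29 tested genes were lower in the mean, with a median of -0.23 (-0.07 in knockout replicate 1 and -0.39 in knockout replicate 2, the array that also held muscle markers at 5.49 above the wild-type mean), including the cytochrome c gene Cycs (-0.67 ± 0.16, SE, n = 2 per group), the citrate cycle gene Idh3a (-0.59 ± 0.19), Cox5a (-0.29 ± 0.10) and Uqcrc1 (-0.37 ± 0.16). Fatty acid oxidation genes went both ways, 14 lower and 6 higher, with Acot1 (2.54 ± 0.13), Acot2 (1.57 ± 0.21, and 0.04 in its other probe set) and Ehhadh (0.88 ± 0.22) higher and the uncoupling protein gene Ucp3 (-0.77 ± 0.14) lower. Hypoxia and glycolysis genes were also mixed, 12 lower and 6 higher, with the glycolytic genes Pfkl (-0.85 ± 0.14) and Ldha (-0.56 ± 0.10) lower and Bnip3 (0.71 ± 0.10) and Pdk1 (0.50 ± 0.09) higher. Of the oxidative phosphorylation list 0 members passed over all genes or adjusted over the list alone. Camera's adjusted p was 0.535 for fatty acid oxidation, where 0 members passed over all genes and Acot1 and Acot2 (higher) and Ucp3 (lower) passed adjusted over the list alone. It was 0.534 for hypoxia and glycolysis, which was called lower without knockout replicate 2 (0.0180), with 0 over all genes, and 4 higher and 5 lower adjusted over the list alone.

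Mast cell and lymphatic endothelial markers rose as groups in the knockout, with camera adjusted p = 1.3e-04 and 0.0246. Both calls were lost, with adjusted p = 0.852 with an estimated correlation. All 6 tested mast cell markers were higher in both knockout arrays, with a median of 0.86 (0.72 and 0.98 in the knockout replicates). These were the protease genes Mcpt4 (1.85 ± 0.10, SE, n = 2 per group), Tpsb2 (0.95 ± 0.21), Cpa3 (0.90 ± 0.18) and Cma1 (0.81 ± 0.15), the histamine-forming enzyme gene Hdc (0.68) and Gata2 (0.60), the last 2 named after their values were seen. Mcpt4 and Cma1 lie among the 200 annotated neighbours on either side of Mmp14. Of 5 lymphatic markers 4 were higher in both knockout arrays, namely Pdpn (1.12 ± 0.32), Reln (0.74 ± 0.09), Fgl2 (0.54 ± 0.10) and the hyaluronan receptor gene Lyve1 (0.41 ± 0.09). The other 1 was lower in both knockout arrays. The list's median was 0.54 (0.55 and 0.54 in the knockout replicates). In the same arrays epidermis and hair follicle markers stood at 2.37 and -0.45 and skeletal muscle markers at -0.71 and 5.49. Blood endothelial markers were 10 lower and 5 higher with a median of -0.13, including Robo4 (-0.62 ± 0.11), Emcn (-0.60 ± 0.10), Kdr (-0.36 ± 0.12) and Ramp2 (0.34 ± 0.14), and 1 of the other Ramp2 probe sets differed by -0.11. No mast cell or lymphatic marker passed over all genes, while 6 mast cell and 4 lymphatic markers passed higher when adjusted over the list alone. For lymphatic endothelium the adjusted p was 0.0656 without knockout replicate 1. Blood endothelium had adjusted p = 0.420, and was called lower without knockout replicate 2 (0.0036), with 0 members passing over all genes, and Emcn and Robo4 lower when adjusted over the list alone.

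Erythroid, macrophage and interferon response genes fell as groups, with camera adjusted p = 0.0029, 0.0246 and 0.0154. All 3 calls were lost, with adjusted p = 0.852 with an estimated correlation. The 4 tested erythroid genes were lower in both knockout arrays, with a median of -1.40, namely the band 3 anion exchanger gene Slc4a1 (-2.08 ± 0.24, SE, n = 2 per group), Bpgm (-1.43 ± 0.09), the heme synthesis gene Alas2 (-1.37 ± 0.36) and the globin gene Hba-a1 (-0.31 ± 0.11). Of 17 macrophage markers 14 were lower, with a median of -0.35, including Fcgr1 (-0.91 ± 0.24), the antigen presentation gene Cd74 (-0.85 ± 0.22), Cd68 (-0.78 ± 0.20) and Mrc1 (-0.38 ± 0.11). All 15 interferon response genes were lower, with a median of -0.35, including Rsad2 (-1.81 ± 0.11), Gbp3 (-0.93 ± 0.29), Ifit2 (-0.43 ± 0.14) and Ddx58 (-0.29 ± 0.13). The wild-type arrays differed in the interferon and macrophage lists as well, with replicate 2 above replicate 1 by medians of 0.45 and 0.26. In knockout replicates 1 and 2 the medians were -1.61 and -1.16 for erythroid, -0.53 and -0.24 for macrophage and -0.41 and -0.26 for interferon genes, beside 2.37 and -0.45 for epidermis and hair follicle and -0.71 and 5.49 for skeletal muscle. B cell, T cell and neutrophil markers had medians of -0.07, -0.01 and 0.03, with members such as Cd79b (-0.24 ± 0.10), Cd247 (-0.30 ± 0.11) and Mmp9 (-0.55 ± 0.16). For neutrophil markers the knockout arrays went opposite ways, with medians of 0.71 in replicate 1 and -0.33 in replicate 2. Cd79b and Cd247 had means of 4.99 and 5.43, near the brightness limit of 4.94, where RMA compresses differences. No member of these lists passed over all genes, and 4 erythroid markers, 0 macrophage markers and, of the interferon list, Rsad2 passed lower when adjusted over the list alone. The macrophage list's adjusted p was 0.124 without wild-type replicate 2 and 0.579 without knockout replicate 1, and that of the interferon list 0.142 and 0.275. Adjusted p-values of the B cell, T cell and neutrophil lists were 0.470, 0.756 and 0.950, with 0 members passing either way.

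Luminal epithelial markers rose as a group (camera adjusted p = 0.0246, but adjusted p = 0.852 with an estimated correlation). Of 18 markers 15 were higher, with a median of 0.54 (0.60 and 0.43 in the knockout replicates), including Foxa1 (1.26 ± 0.52, SE, n = 2 per group), the adhesion molecule gene Epcam (1.04 ± 0.36), the luminal regulator gene Gata3 (0.98 ± 0.38) and the receptor gene Kit (0.45 ± 0.16). Wild-type replicate 2 differed from wild-type replicate 1 by a median of -0.76, which is larger than the difference between genotypes. Another Epcam probe set of similar brightness differed by -0.10. Of 13 basal epithelial markers 10 were higher, with a median of 0.65 (0.64 and 0.16 in the knockout replicates), including Col17a1 (0.76 ± 0.30), Itgb4 (0.66 ± 0.14) and Cdh3 (0.27 ± 0.09), whereas Itga6 was lower (-0.52 ± 0.10). Genes of mammary branching signals were 13 higher and 8 lower with a median of 0.14, among them Wnt4 (0.78 ± 0.19), the hepatocyte growth factor receptor gene Met (0.71 ± 0.12), Ntn1 (0.53 ± 0.13) and Wnt2 (-0.44 ± 0.12). No luminal marker passed over all genes or adjusted over the list alone. The luminal list's adjusted p was 0.306 without wild-type replicate 2, 0.0931 without knockout replicate 1 and 0.0703 without knockout replicate 2. With all 4 arrays basal epithelium (adjusted p = 0.122) and branching signals (0.217) were not called, with 0 members passing over all genes or adjusted over the list alone. With 1 array left out, basal epithelium was called higher without wild-type replicate 1 (0.00895) or knockout replicate 2 (0.0220), and branching signals without knockout replicate 2 (0.0464). Skin keratinocytes express many of the basal markers, and epidermis and hair follicle markers stood at 2.37 in knockout replicate 1, the lone knockout array in the last setting, and at -0.45 in knockout replicate 2.

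Cell cycle genes were called lower by camera (adjusted p = 0.0332, but adjusted p = 0.852 with an estimated correlation), and the knockout arrays lay far apart. Of 34 genes 33 were lower in the mean, with a median of -0.68, but the median stood at 0.28 above the wild-type mean in knockout replicate 1 and at -1.63 in knockout replicate 2. Cdc6 (-0.64 ± 0.23, SE, n = 2 per group), the cyclin gene Ccne1 (-0.38 ± 0.15), Mcm2 (-0.73 ± 0.36) and Mcm5 (-0.96 ± 0.52) had the smallest p. Skeletal muscle markers moved with the same array, at a median of 5.49 above the wild-type mean in knockout replicate 2 and -0.71 in knockout replicate 1. Myh4, the gene of a fast myosin heavy chain, had 4.09, 4.15 and 4.21 in the other arrays and 12.4 in knockout replicate 2, followed by Pvalb (10.6), Actn3 (10.4) and Myoz1 (9.70). The muscle markers also stood higher in wild-type replicate 2 than in replicate 1 by a median of 1.02. Epidermis and hair follicle markers did the opposite in the median, at 2.37 in knockout replicate 1 and -0.45 in knockout replicate 2. In these arrays Lor had 8.65 and 4.01, Sbsn 9.79 and 8.46, Krtdap 8.84 and 7.11 and Krt79 8.07 and 5.97. The knockout mean minus the wild-type mean was 2.32 for Lor, 1.56 for Sbsn, 1.08 for Krtdap and -1.13 for Krt79. Against the wild-type mean Krt79 was thus not raised in knockout replicate 1, while Sbsn and Krtdap were not lowered in knockout replicate 2. Without knockout replicate 2 camera called the cell cycle list higher, with a median of 0.28 and an adjusted p of 0.0103. Skeletal muscle had adjusted p = 0.0543 and epidermis and hair follicle 0.217, which was called higher without knockout replicate 2 (5.2e-05). No member of these 3 lists passed over all genes or adjusted over the list alone. For muscle the adjusted p was 1.3e-09 without knockout replicate 1 and 0.0027 without wild-type replicate 2.

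Extracellular matrix lists showed no shift that passed with all 4 arrays. Of 23 matrix metalloproteinase and inhibitor genes 11 were higher and 12 lower. The gelatinase gene Mmp2 had 9.50 and 9.39 in wild type and 10.4 and 11.6 in the knockout (1.56 ± 0.41, SE, n = 2 per group), and Mmp11 had 5.71 and 5.82 against 7.46 and 9.27 (2.60 ± 0.65). Adamts5 (-1.80 ± 0.12) and Adamts9 (-0.76 ± 0.15) were lower, with 1 further Adamts9 probe set close to 0. Of 13 fibrillar and associated collagen genes 10 were lower, with a median of -0.33, among them Col15a1 (-1.41 ± 0.60), Col14a1 (-0.42 ± 0.12), Col5a2 (-0.33 ± 0.12) and Col6a1 (-0.29 ± 0.13). Of 23 genes of collagen processing and matrix glycoproteins 16 were lower, with Loxl3 (-0.81 ± 0.16), Plod3 (-0.39 ± 0.11) and the fibronectin gene Fn1 (-0.37 ± 0.10) lower and the tenascin gene Tnc (0.38 ± 0.10) higher. Basement membrane genes were 8 lower and 6 higher, with Col4a1 (-0.37 ± 0.13), Col4a2 (-0.32 ± 0.11), Col18a1 (-0.34 ± 0.14) and Hspg2 (-0.34 ± 0.13, and 0.10 in its other probe set). Among 15 integrins and collagen receptors 9 were higher and 6 lower, including Sdc4 (0.63 ± 0.11), Itga1 (-1.15 ± 0.25), Itgb5 (-0.56 ± 0.11) and Itgb1 (-0.32 ± 0.10).

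Camera's adjusted p-values were 0.756 for matrix metalloproteinases and inhibitors, 0.103 for fibrillar collagens, 0.122 for collagen processing, 0.743 for basement membrane and 0.776 for integrins. Fibrillar collagens were called lower without wild-type replicate 2 (0.0314) or knockout replicate 1 (0.0336), and collagen processing lower without wild-type replicate 2 (0.0388) or knockout replicate 2 (0.0212). No member passed over all genes. Adjusted over the list alone, Adamts5 and Itgb5 passed lower and Sdc4 higher. For matrix metalloproteinases the median was -0.02 and the mean 0.03, with camera's direction lower, and for integrins the median was 0.13 and the mean -0.05, with camera's direction higher.

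Genes of the growth hormone and insulin-like growth factor axis were 12 higher and 5 lower. The insulin receptor gene Insr (1.28 ± 0.12, SE, n = 2 per group), its substrate gene Irs1 (0.91 ± 0.10), the imprinted gene Peg3 (1.13 ± 0.10) and Igf1r (1.07) were higher, and Igfals, which encodes a carrier subunit of circulating growth factor, was lower (-1.85 ± 0.26). Camera's adjusted p was 0.0881, 0 members passed over all genes, and these 4 higher and 1 lower passed adjusted over the list alone. Glucocorticoid response genes were 10 higher and 4 lower (adjusted p = 0.0881), with Cdkn1c (0.82 ± 0.12), Mt1 (0.90 ± 0.20, and -0.02 in its other probe set) and Map3k6 (0.56 ± 0.17) higher and Tsc22d3 lower (-0.33 ± 0.10), and Cdkn1c alone passed over the list. That list's adjusted p was 0.0337 without wild-type replicate 2 and 0.0321 without knockout replicate 1.

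The remaining signalling and stress lists had camera adjusted p-values from 0.217 to 0.577. Notch pathway genes (0.434) were 11 lower and 3 higher, with Heyl (-0.89 ± 0.13, SE, n = 2 per group), Notch4 (-0.58 ± 0.09) and Dll4 (-0.53 ± 0.11) lower and Notch1 (0.68 ± 0.09) higher. Wnt pathway genes (0.286) included Fzd4 (-1.19 ± 0.18), Sfrp2 (-0.79 ± 0.13), Fzd7 (0.75 ± 0.17) and Tcf7l2 (0.71 ± 0.17). The p53 and senescence list (0.434) held the cell cycle inhibitor gene Cdkn2b (-1.54 ± 0.16), Phlda3 (-0.81 ± 0.10), Plk2 (-0.37 ± 0.09) and Trp53inp1 (0.47 ± 0.11), and the Yap target list (0.577) held Gadd45b (0.85 ± 0.13), Ptpn14 (0.80 ± 0.09), Wwc1 (0.60 ± 0.11) and Ajuba (-0.42 ± 0.10). In the amino acid stress list (0.420) Chac1 (1.16 ± 0.25), Pck2 (0.57 ± 0.10) and Ppp1r15a (0.51 ± 0.11) were higher and Atf5 (-0.46 ± 0.09) lower. These 20 genes did not pass over all genes but passed adjusted over their list alone. Schwann cell and nerve markers (0.217) were split, with the myelin gene Mbp (0.83 ± 0.11) and Mal (0.87 ± 0.11) higher and S100b (-2.13 ± 0.47) and Ngfr (-0.58 ± 0.10) lower, and all 4 passed over the list alone. For the Yap list the median was -0.04, the mean 0.09 and camera's direction higher.

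In the other lists of this range 2 genes passed adjusted over the list alone, Twist2 (0.84 ± 0.11, SE, n = 2 per group) among fibroblast and preadipocyte markers and the chemokine gene Cxcl12 (1.02 ± 0.15, but -0.17 in its other probe set) among inflammatory mediators. The fibroblast list (0.563) also held Clec3b (-0.95 ± 0.22), and the inflammatory list (0.539) held Ccl5 (-1.36 ± 0.41) and Ccl2 (-0.90 ± 0.20). Unfolded protein response genes (0.256) included the chaperone gene Hspa5 (-0.45 ± 0.09) and Manf (-0.88 ± 0.26). Circadian clock genes (0.463) included Per3 (1.02 ± 0.25) and Tef (1.02 ± 0.24), immediate early genes (0.470) Klf2 (0.43 ± 0.10) and Klf6 (-0.55 ± 0.17), the transforming growth factor beta list (0.477) Id1 (0.64 ± 0.18) and Ltbp2 (-0.33 ± 0.10), and pericyte and smooth muscle markers (0.577) Kcnj8 (-0.53 ± 0.12) and Rgs5 (-0.45 ± 0.11). In the pericyte list the median was near 0 and the mean -0.07, with camera's direction lower. No member of these lists passed over all genes.

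Camera called 11 of 42 lists, 3 higher and 8 lower. It called 16 without knockout replicate 2, 12 without either wild-type replicate and 9 without knockout replicate 1. Fry called 2, lymphatic endothelium and erythroid cells, each with an adjusted p of 0.0180. With an estimated correlation 0 lists were called, and the smallest unadjusted camera p was 0.0681. That setting also missed the shifted list of the simulation.

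**Figure D3:**
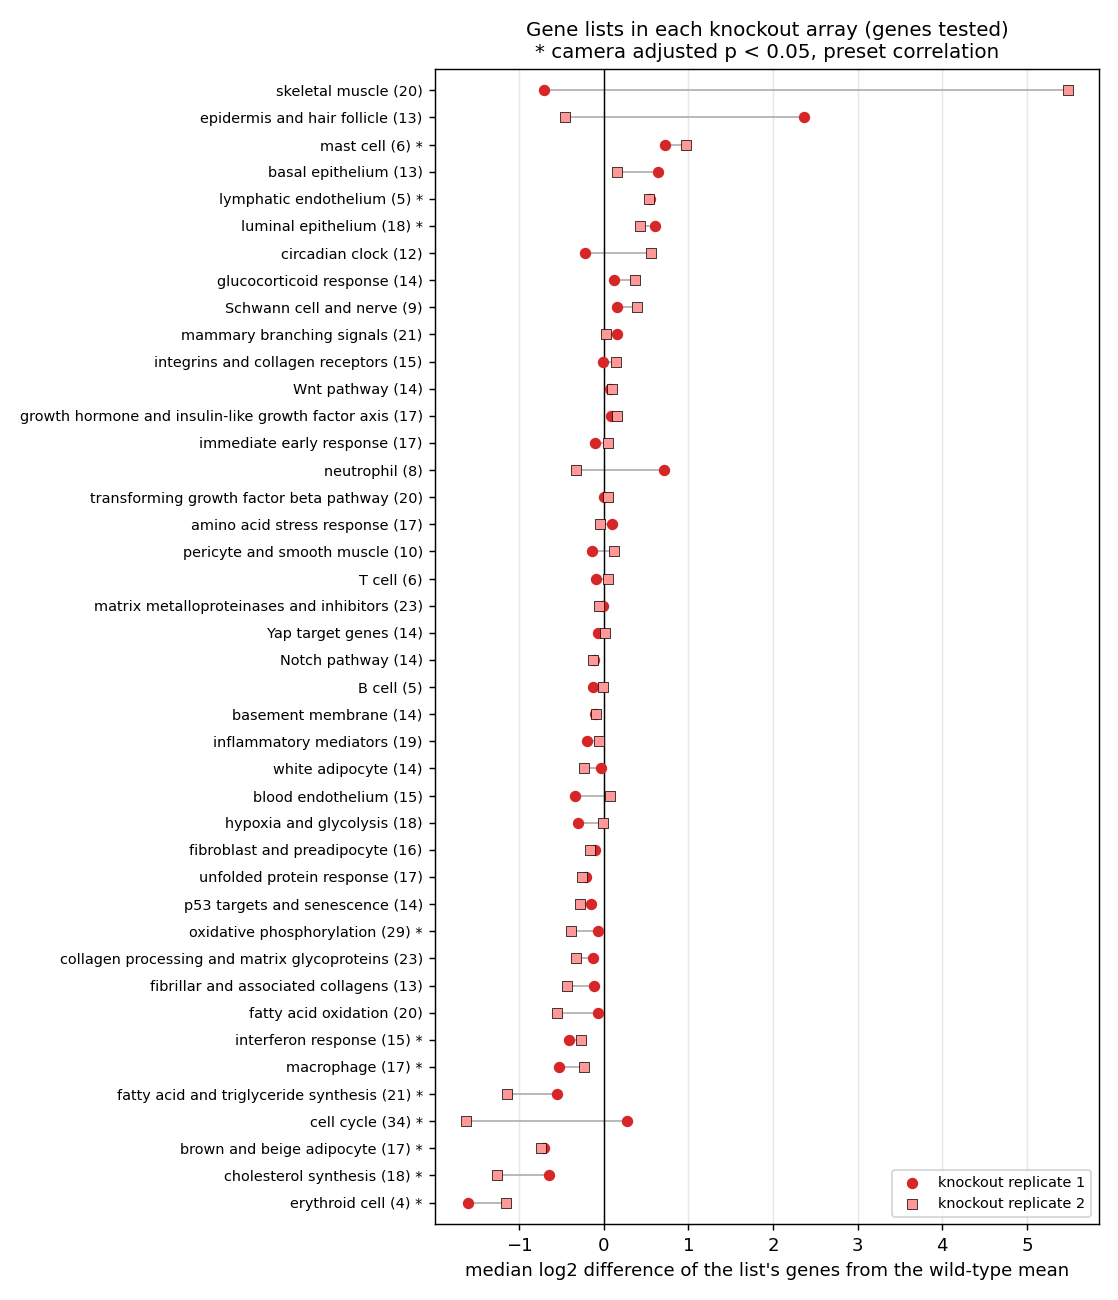
Median log2 difference from the wild-type mean (horizontal axis) of each gene list (vertical axis, with the number of genes tested) in knockout replicate 1 (circles) and knockout replicate 2 (squares). Grey lines join the arrays and asterisks mark lists that camera called with the preset correlation. The arrays lie far apart for skeletal muscle (-0.71 and 5.49), epidermis and hair follicle (2.37 and -0.45) and cell cycle (0.28 and -1.63), and close together for brown and beige adipocyte (-0.71 and -0.74).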

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

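The tests on muscle tissue, RNA degradation, array scaling, adipocyte number, linkage and skin in this part were chosen only after the results were seen.

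Probe sets without a gene in the annotation were left out of the comparisons, yet some carried large differences. Of 5868 such probe sets above the brightness limit, 6 had both knockout arrays above both wild-type arrays with at least a 4-fold difference and 15 were at least 4-fold lower, against 16 and 36 of the 11078 named genes. The probe set with the smallest p had 8.14 and 8.10 in wild type and 4.17 and 4.31 in the knockout, and its adjusted p of 0.0484 in limma, with Benjamini-Hochberg adjustment over single probe sets, was the only one under 0.05 in that test.

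Skeletal muscle genes stood high in knockout replicate 2, and muscle tissue in that sample is a candidate source. Of the 20 tested markers 17 lay at least 4-fold above the highest other array, against 0.542% of all genes, with Acta1 at 13.0, Tnnc2 at 12.9 and Ckm at 12.0, while Myh1, Mb and Myh3 did not; 0 of the 20 belong to another list. RNA degradation is argued against, because the actin 3-prime minus 5-prime difference was 0.565 there, 0.612 in knockout replicate 1, which lacked the muscle signal, and 0.459 and 0.508 in wild type. For array scaling, the median excess over the other arrays was 5.84 after cyclic loess and 5.80 before. RMA had already equalised the arrays, and loess could hardly remove a large excess confined to few genes. That comparison therefore does not decide on array scaling. The gland lies next to the body wall, so dissection may have carried muscle along, and wild-type replicate 2 held a lesser excess. A difference in the tissue of that animal was not tested and stays open.

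Lower expression of lipid synthesis, sterol synthesis and brown adipocyte genes could reflect fewer adipocytes or the muscle in knockout replicate 2. The median of 14 white adipocyte markers was -0.13 (95% bootstrap interval over markers, not animals, -0.21 to 0.04) against -0.79 for the 56 genes of these lists. The gap between these medians was favoured in advance, as the 56 genes came from called lists and the white markers did not. In these samples the white adipocyte median of -0.13 by itself argues against a loss of adipocytes as a whole. In knockout replicate 1, which lacked the muscle signal but held epidermis and hair follicle markers at 2.37, the lists' median was -0.61. That was below the -0.09 at the 2.5th percentile of 10000 matched random lists. Camera had called the lists lower with this array included, which favoured such a position in advance. The comparison with unselected random lists is therefore not independent support. In knockout replicate 2 the lists' median was -0.93 against -0.23 for white adipocyte markers (interval over markers -0.37 to -0.07). The same selection favoured this gap, so it does not decide on muscle in that array. In these samples muscle is argued against only as the whole cause, because the lists were also lower in knockout replicate 1. The genotype itself, fewer brown or beige adipocytes, skin in knockout replicate 1, and the feeding and growth of the pups stay open and were not separated.

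Higher mast cell markers may come from alleles linked to Mmp14 in an outbred background, since Mcpt4 and Cma1 are among its neighbours, or from skin in the samples. For these 2 markers linkage cannot be told apart from an effect of the knockout, as 59.7% of 67 other neighbouring genes and 58.8% of the remaining genes had no overlap of the groups (Fisher's exact test, two-sided, p = 0.902). For the 4 markers elsewhere, Cpa3, Tpsb2, Hdc and Gata2, with a median of 0.79, linkage to the Mmp14 locus is argued against as a direct cause, because 0 of them lie on its chromosome. More epidermis and hair follicle is argued against as the source in knockout replicate 2. Their median there was -0.45 (95% bootstrap interval over markers, not animals, -2.18 to -0.02) and the mast cell median 0.98. Single members went both ways there, with Sbsn and Krtdap above the wild-type mean and Krt79 below. In knockout replicate 1, where the epidermis and mast cell medians were 2.37 and 0.72, skin is not argued against. The epidermis and hair follicle list holds no markers of dermis or other connective tissue, so these were not tested in either array. Fibroblast and preadipocyte markers stood at -0.11 and -0.16 in knockout replicates 1 and 2, and fibrillar collagen genes at -0.12 and -0.43. Neither list was thus raised in the median, although 6 of 16 fibroblast and 3 of 13 collagen genes were higher in the mean. Skin in knockout replicate 1, dermis or other connective tissue in either array, more mast cells, more transcript per cell, unlinked alleles and an effect of genotype stay open. Skeletal muscle markers stood at -0.71 and 5.49 in knockout replicates 1 and 2, and muscle was not tested as a source.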

How the results depend on the processing

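The alternative without genes near Mmp14 was chosen only after the data were seen; the others were planned. Limma called 0 genes in each direction under every filter, choice of probe sets, scaling and variance model tried, and with a 2-fold minimum as well. An adjusted p limit of 0.10 gave 7 higher and 10 lower, and with all 4 arrays 0 and 0 with array weights or a replicate block, 126 and 146 after cyclic loess, 139 and 164 after quantile normalization and 163 and 196 with the 75th percentile filter. Under that limit 0 and 0 came without either wild-type array, 2123 and 3501 without knockout replicate 1 and 1650 and 1360 without knockout replicate 2. At 0.05, single probe sets gave 0 higher and 1 lower. Leaving out 1 array gave 0 to 1455 genes higher and 0 to 2725 lower. The calls came without knockout replicate 1 (1455 and 2725) or knockout replicate 2 (746 and 553), which leave the closely matched wild-type pair to set the spread, while 0 were called without either wild-type array. The Mmp14 difference ranged from -3.17 to -2.97 with 1 array left out, where it passed without knockout replicate 1 (-3.15) or knockout replicate 2 (-2.99). It was -2.37 for the mean of its probe sets, -1.67 for the dimmer one and -3.10 to -3.05 under other scalings, and did not pass there. All 20 other genes named in the comparison of single genes kept their direction in each setting that tested them. Camera called 11 lists, 7 with the 75th percentile filter, which tests fewer genes (6 of them among the 11), 6 without probe sets that can match several transcripts (6 of the 11), 0 with an estimated correlation and 2 with fry, a test with another null hypothesis. Without probe sets that can match several transcripts, mast cell and erythroid lists kept 1 and 2 genes, fewer than the 3 a test needs, and the cell cycle, luminal and macrophage lists were not called (adjusted p = 0.0899, 0.126 and 0.157), a cause not tested. Over other filters, scalings and models that count was 9 to 13, and 11 without genes near Mmp14. Camera takes no robust prior, so that setting was not run for lists. With 1 array left out it was 9 to 16. The cell cycle list turned, from a median of -1.63 without knockout replicate 1 to 0.28 without knockout replicate 2, which shows that knockout replicate 2 set its direction. With the replicate number as a block, 0 genes were called higher, 0 lower and 14 lists were called, with all 11 among them; nothing in the labels says that the numbers pair animals, and deviations of same-numbered arrays correlated at -0.0885 across genes. Genes near the array background, such as H3c15 at 4.19 and 4.07 in the knockout, have the least certain folds. Other named genes also had means near the brightness limit of 4.94. Among them were Cdh3 (5.01), Hmgcs1 (5.07), Cdc6 (5.26), Pou3f1 (5.26), Gata3 (5.27), Fcgr1 (5.30), Ccne1 (5.34), Dll4 (5.37), Col17a1 (5.40) and Dio2 (5.43).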

Other observations

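The genes in the next paragraph were singled out after their values were seen. The test of FoxO-related genes was prompted by the lipid result and written before the group was examined, except that Pdk4 and Sesn1 are in gene lists whose values had been seen.

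Several large differences lay outside the gene lists. The protease inhibitor gene Serpina1b had 12.0 and 11.3 in wild type and 7.37 and 4.80 in the knockout (log2 -5.57 ± 0.95, SE, n = 2 per group). The prostaglandin receptor gene Ptger3 (9.62 and 9.52 against 7.03 and 6.11), the natriuretic peptide clearance receptor gene Npr3 (-2.64 ± 0.52), the vascular peptide gene Apln (-2.62 ± 0.44) and the insulin-induced gene Angptl8 (-1.89 ± 0.19) were also lower in both knockout arrays. Higher in both were the pantetheinase gene Vnn1 (3.17 ± 0.35), the sialyltransferase gene St3gal6 (2.60 ± 0.24), the antioxidant enzyme gene Gpx3 (2.45 ± 0.61), the fatty acid transporter gene Slc27a1 (2.40 ± 0.23) and the cytochrome gene Cyp2e1 (2.28 ± 0.48). In limma none of these passed after Benjamini-Hochberg adjustment, with adjusted p-values of 0.101 for Slc27a1 and 0.163 for Gpx3.

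Lower lipogenic gene expression beside higher Insr (1.28) and Irs1 (0.91) prompted the hypothesis that insulin signalling may have been lower in the knockout glands. Genes that FoxO factors switch on when insulin is low would then be higher in each knockout array. Of 17 such genes 14 were tested, and their median difference was 0.53. It was 0.60 in knockout replicate 1 and 0.33 in knockout replicate 2, above the 0.18 and 0.13 at the upper end of the central 95% of 10000 random lists matched on mean expression. For the 12 genes in no gene list these medians were 0.60 and 0.48, against 0.20 and 0.15. The random lists held independently drawn genes, whose medians can vary less than those of co-regulated genes. Standing above them in an array does not measure the spread between animals. Both knockout arrays lay above both wild-type arrays for 9 of the 14, against 26.3% of all tested genes and 16.7% by chance, among them Klhl24 (1.35), Cited2 (0.97), Txnip (0.83) and Foxo3 (0.71), and below for 1, Bcl6 (-0.78). The values are in line with the hypothesis but do not separate it from less feeding, slower growth or other stress that acts through the same genes, nor from a different tissue content, as epidermis and hair follicle markers stood at 2.37 in knockout replicate 1 and skeletal muscle markers at 5.49 in knockout replicate 2.

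Y-linked genes were too dim to test in any array. Eif2s3y had 3.65 and 3.74 in wild type and 3.75 and 3.88 in the knockout at its brighter probe set, while the brightest Xist probe set had 12.0 and 12.1 against 12.3 and 12.4. Control probe sets for Gapdh had 12.1 at the 3-prime end in knockout replicate 2 and 11.6, 11.5 and 11.3 in the other arrays. The 3-prime minus 5-prime difference was lower in both knockout arrays for Gapdh (0.0971 and 0.119 against 0.185 and 0.175) and higher for actin (0.612 and 0.565 against 0.459 and 0.508).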
